A study of Mus musculus with 2 samples.

How the data were processed

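Small RNA libraries were made from total RNA of hearts of female B6CASTF1/J mice aged 36 days, per the labels, which give a size range under 30 and point to a protocol for multiplexed miRNA libraries. The series holds 1 group of 2 libraries, biological replicates 1 and 2, each with technical replicate 1. Each comes from a heart with its own biosample record, while both records carry 1 shared donor code. One free-text label gives the age in months and the age field gives days; the day value is used here.

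The authors deposited raw read counts per GENCODE M21 miRNA gene on the mouse build mm10, per the deposited notes. Each file holds 3 columns of counts, without regard to strand, on the gene's strand and on the opposite strand, over 2202 miRNA genes and 4 rows that name no gene. The aligner and the counting program are not given in the sources used here. Reads that mapped to several places stand in a row of their own and are part of no gene's count, so a miRNA encoded identically by several gene copies can be counted low or not at all. In the column without regard to strand, reads at genes overlapped by a miRNA gene on the other strand stand in an ambiguous row, so the sense-strand column was used throughout.

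The count tables account for 5606848 reads in replicate 1 and 4990632 in replicate 2. Of these, 2074961 and 1766135 reads were assigned to miRNA genes, and these totals served as library sizes. Values in CPM are sense-strand counts per 1000000 sense-strand counts over gene rows, so that 1 read equals 0.482 CPM in replicate 1 and 0.566 CPM in replicate 2. A count of 0 allows up to 3 counts, which is 1.45 CPM in replicate 1 and 1.70 CPM in replicate 2. Intervals are exact (Clopper-Pearson) at the 95% level. Reads made by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

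All 2202 gene IDs matched GENCODE M21, which gave symbols, coordinates (mm10, 1-based), hairpin sequences and host genes. A gene was called detected at 2 CPM or more in both libraries. Log2 ratios are replicate 2 over replicate 1 on sizes scaled by the trimmed mean of M values (TMM, edgeR 4.0.16), with a prior count of 0.5. Each gene with 10 or more counts over both libraries was tested with an exact two-sided binomial test of the split of its counts, with Benjamini-Hochberg adjustment and a threshold of 0.05. That test compares 2 libraries beyond counting error and not conditions. The biological coefficient of variation came from edgeR's common dispersion with an intercept-only design over genes with a mean of 2 CPM or more, and DESeq2 1.42.0 gave an alternative. The deposited counts of the 2 libraries were also compared by a chi-square test over genes to ask whether one library had been deposited as 2 files.

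Before the data were examined, 20 gene lists were fixed for cardiac and striated muscle, skeletal muscle, endothelial, smooth muscle, fibroblast, erythroid, immune, liver, neuronal, epithelial and endocrine, embryonic, testis and stress-related miRNA genes, the let-7, miR-30, miR-29 and miR-15 families, and the miR-17, Dlk1-Dio3 and Sfmbt2 clusters. The Sfmbt2 list holds every symbol that starts with Mir297, Mir466, Mir467 or Mir669, without regard to position. Some genes are in 2 lists. The level of a list was placed among 10000 random lists of the same size from all measured genes. Its median log2 ratio was placed among 10000 random lists matched on 10 bins of mean CPM, and the central range is the 2.5 to 97.5 percentile. Random lists draw genes independently, so percentiles do not allow for members that share a locus or a family. Neighbouring genes were 2 consecutive genes of 1 strand within 10 kb, with a mean of 10 CPM or more and different family numbers, and were tested with 100000 shuffles.

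The rule for named genes took the 20 genes with the highest mean CPM, up to 4 detected members of each list (or its highest member where none was detected), and, among genes with 50 or more counts and an adjusted p under 0.05, the 5 with the largest log2 ratio in each direction. It gave 81 genes. Genes outside it are said to have been chosen after their values were seen, apart from genes found by the scan of opposite-strand reads.

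The alternatives fixed in advance were other detection limits, each library alone, the counts without regard to strand, library sizes over all reads, the deeper library thinned to the depth of the shallower, other filters and pseudocounts, DESeq2 size factors, library size alone, single-copy genes and other settings of the neighbour test. Alternatives without the erythroid list, without the erythroid and embryonic lists, and without genes that share a run of 18 nt with another hairpin were chosen after seeing the data. The scripts were tested on simulated data. In 2 simulated libraries of 359 tested genes, the per-gene test recovered 52 of 95 genes changed 1.5-fold and 92 of 100 changed 4-fold, and called 1 of 164 unchanged genes. These simulated counts held counting error only and no spread between animals, so the rates do not carry over to the 2 hearts. The neighbour test called 1 of 40 simulations without and 40 of 40 with a shared effect, over 264 genes. Over 300 simulated genes, the list comparison left the central range in 4 of 40 simulations without an effect and in 32 of 40 with a shift of 1 on the log2 scale. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3. With 1 group there is no comparison between conditions.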

Results

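The series measured miRNA genes by small RNA sequencing in the hearts of 2 female mice aged 36 days, of a cross between C57BL/6 and CAST strains. It forms 1 group with n = 2, so the design asks which miRNA genes are abundant in this tissue and how far the 2 hearts agree. miRNAs are short RNAs cut from hairpin transcripts. Of all reads, 37.0% (95% exact interval 37.0 to 37.0) in replicate 1 and 35.4% (35.3 to 35.4) in replicate 2 were assigned to miRNA genes. A further 42.0% (42.0 to 42.0) and 39.8% (39.7 to 39.8) mapped to several places and were counted at no gene. Reads outside miRNA genes made up 5.82% (5.80 to 5.84) and 8.35% (8.33 to 8.37), and unmapped reads 15.2% (15.1 to 15.2) and 16.5% (16.4 to 16.5). The 2 libraries were not 1 library deposited as 2 files: a chi-square test of their counts over 350 genes gave 150256 with 349 degrees of freedom.

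A few miRNA genes made up most of the reads assigned to miRNA genes. Reads that mapped to several places are outside this ranking, so a miRNA encoded identically by several gene copies can rank too low or be missing. Mir378a, in an intron of Ppargc1b (a coactivator of mitochondrial gene expression), held 14.6% ± 2.87 (SD, n = 2) of the counts, the top 10 genes 66.6% ± 0.787 and the top 20 genes 83.9% ± 0.302. In replicate 1, 32 genes made up 90% of the counts, and 31 did in replicate 2. Mir378a (chromosome 18, 61397835 to 61397900, minus strand) reached 146001 ± 28746 CPM. Next came Mirlet7i with 84244 ± 14677 CPM, Mir126a with 81414 ± 22066 CPM, Mirlet7g with 61610 ± 17205 CPM and Mir23b with 54688 ± 2933 CPM. Mir126a (chromosome 2, 26591357 to 26591429, plus strand) lies in the endothelial gene Egfl7. Then followed Mir99a, Mirlet7b, Mir23a, Mirlet7d and Mir143, between 51387 ± 7313 and 42177 ± 267 CPM. Mir139, Mir26b, Mir451a, Mir149, Mir30d, Mir99b, Mir22, Mir191, Mir30a and Mir100 completed the top 20, from 30472 ± 13267 CPM for Mir139 to 8740 ± 1967 CPM for Mir100. Of 2202 miRNA genes, 335 were detected at 2 CPM or more in both libraries, 131 reached 100 CPM in both and 17 reached 10000 CPM in both.

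Among the genes of heart and striated muscle, the 3 miRNA genes inside myosin heavy chain genes had higher CPM than those of the miR-1 and miR-133 families. Mir208a, in an intron of Myh6 (the alpha myosin heavy chain of the adult mouse heart; chromosome 14, 54949060 to 54949142, minus strand), reached 4439 ± 891 CPM (SD, n = 2). Mir499, in an intron of Myh7b (chromosome 2, 155622880 to 155622958, plus strand), reached 2844 ± 892 CPM, and Mir208b, in an intron of Myh7 (the beta myosin heavy chain), 139 ± 25.7 CPM. Mir208a exceeded Mir208b by 31.6 times (exact interval 27.9 to 36.0) in replicate 1 and 32.3 times (28.7 to 36.6) in replicate 2. Mir1a-2 had 121 and 66 counts. Mir1a-1 (8 and 7 counts), Mir133a-1 (8 and 2), Mir133a-2 (2 and 2), Mir133b (2 and 10) and Mir1b (0 and 3), chosen after their values were seen, lay near the floor. Reads that map to several copies are outside these counts, so the low values of Mir1a and Mir133a genes do not give the level of their mature miRNAs. The list had 5 of 9 members detected, and its median of 3.91 CPM stood at the 99.4 percentile of random lists. Most measured genes had no count, so a median near the floor can stand that high. Of the skeletal muscle list, Mir206 was detected with 7 and 17 counts.

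**Figure D1:**
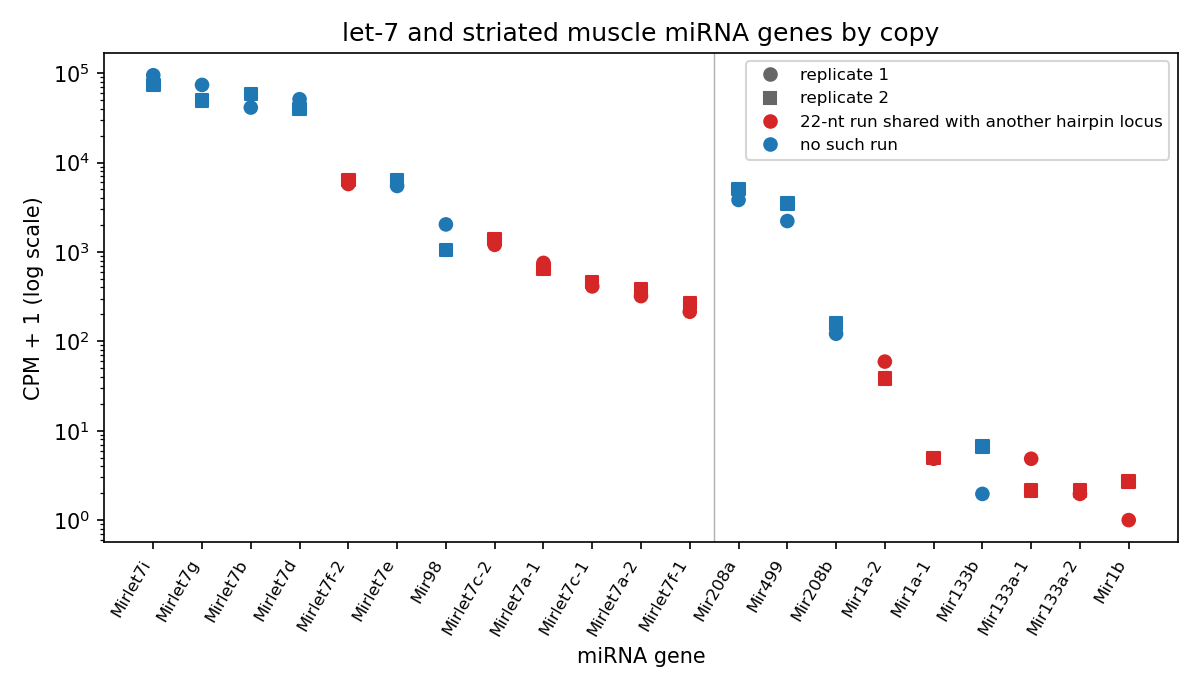
CPM + 1 (log scale) of the 12 let-7 genes and the 9 genes of the cardiac and striated muscle list, as a circle for replicate 1 and a square for replicate 2. Red genes share a run of 22 nt with another hairpin locus and blue genes do not; among let-7 genes the red ones reach at most 6071 CPM and the blue ones up to 84244 CPM on average.

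Vessel, fibroblast and immune miRNA genes were detected in both hearts. The endothelial list (3 of 4 members detected) summed to 82973 ± 22749 CPM, nearly all from Mir126a, with Mir221 at 1499 ± 684 CPM and Mir222 at 59.7 ± 1.26 CPM. The smooth muscle list (2 of 2) summed to 43675 ± 788 CPM, from Mir143 and Mir145a (1497 ± 521 CPM). The fibroblast list (4 of 5) reached 3144 ± 771 CPM, led by Mir21a with 1767 ± 187 CPM and Mir214 with 1346 ± 593 CPM. Mir199b stood at 24.4 ± 10.5 CPM and Mir199a-2 at 7.10 ± 1.18 CPM. Both share a run of 22 nt with another hairpin, so their counts do not give the level of the mature miRNAs. The immune list (5 of 6) reached 5966 ± 733 CPM, led by Mir155 (2903 ± 406 CPM), Mir150 (1463 ± 696 CPM), Mir146 (1180 ± 207 CPM) and Mir142 (359 ± 198 CPM). All 3 measured erythroid genes were detected, at 26739 ± 27082 CPM in sum, a spread as large as the mean.

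Broadly expressed families were also abundant. All 12 let-7 genes were detected and together held 27.7% of counts in replicate 1 and 23.8% in replicate 2. All 6 miR-30 genes summed to 34991 ± 3957 CPM, led by Mir30d, Mir30a and Mir30e (6293 ± 8.69 CPM), with Mir30c-2 at 899 ± 41.4 CPM. The miR-15 list (7 of 7) summed to 12080 ± 2252 CPM, the miR-17 clusters (10 of 15), led by Mir93, to 13368 ± 1135 CPM and miR-29 (4 of 4), led by Mir29a, to 3981 ± 587 CPM. Of the imprinted Dlk1-Dio3 cluster on chromosome 12, 36 of 43 genes were detected, with a sum of 4543 ± 66.3 CPM, led by Mir127 (1849 ± 96.9 CPM), Mir411, Mir379 and Mir541. Of the Sfmbt2 list, taken by symbol and not by position, 7 of 81 genes were detected, with a sum of 1063 ± 32.3 CPM. The highest were Mir467d (692 ± 56.8 CPM), Mir467e, Mir669c and Mir669o, all in introns of Sfmbt2 on chromosome 2. Of the 81 hairpins, 80 share a run of 18 nt with another hairpin. Reads that map to several places are left out, so these counts can be too low. The stress-related list (9 of 10) summed to 57070 ± 3398 CPM, mostly from Mir23a, with Mir34a at 1936 ± 982 CPM.

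Genes typical of other tissues were counted as well. The liver list (4 of 4 detected) summed to 113 ± 4.86 CPM, with Mir122 at 44.8 ± 18.5 CPM, Mir192 at 35.3 ± 7.70 CPM, Mir194-1 at 19.2 ± 3.29 CPM and Mir194-2 at 13.4 ± 2.63 CPM. The neuronal list (3 of 9) summed to 132 ± 81.7 CPM, with Mir128-1, Mir137 and Mir128-2 detected. Of its 9 members, 8 share a run of 18 nt with another hairpin, so their counts do not give the level of the mature miRNAs. The epithelial and endocrine list (8 of 8) summed to 546 ± 252 CPM, with Mir200c at 327 ± 146 CPM and Mir203 at 84.3 ± 3.32 CPM. The embryonic list (1 of 11, Mir302d) summed to 12.0 CPM in replicate 1 and 201 CPM in replicate 2, and the testis list (1 of 10, Mir470) to 11.9 ± 0.853 CPM. Most measured genes had no count, so a list with a few counts can stand high among random lists: the embryonic and testis medians stood at the 99.8 and 95.1 percentiles. The neuronal and Sfmbt2 lists stood at the 45.9 and 50 percentiles and the skeletal muscle list at the 77.0 percentile; the other lists stood at the 96.2 percentile or above.

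**Figure D2:**
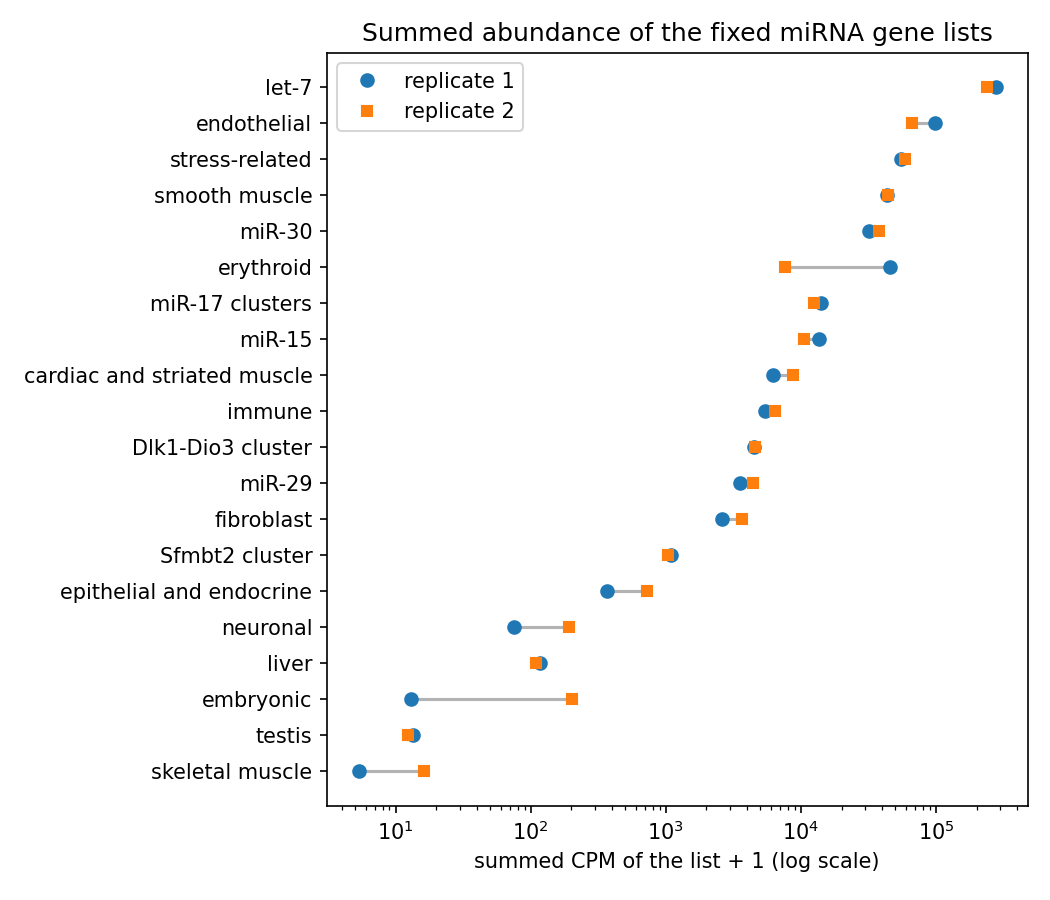
Summed CPM + 1 (log scale) of each of the 20 fixed gene lists, as a circle for the replicate 1 heart and a square for the replicate 2 heart. The erythroid list lies at 45889 CPM in replicate 1 and 7589 CPM in replicate 2, and the embryonic list at 12.0 and 201 CPM.

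Across the 374 genes with a mean of 2 CPM or more, Pearson's r of log2(CPM + 1) was 0.967 and Spearman's rho 0.944; these are across genes, which are not independent replicates. The SD of the log2 ratio was 1.13, against 0.44 from counting alone; the spread between 2 animals holds more than counting error, so this does not single out any gene. Agreement depended on the level. From 2 to 10 CPM (110 genes) r was 0.124, the SD 1.22 and the share of genes that differed 2-fold or more 33.6%; from 10 to 100 CPM (124 genes) 0.483, 1.39 and 20.2%. From 100 to 1000 CPM (70 genes) they were 0.735, 0.80 and 14.3%, and at 1000 CPM or more (70 genes) 0.943, 0.68 and 10%. Within a class, the narrow range of levels also lowers r. The biological coefficient of variation was 40.5% with edgeR's common dispersion; the median DESeq2 gene-wise dispersion gave 10.8%.

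The largest differences are given among genes with 50 or more counts over both libraries and an adjusted p under 0.05. The 5 genes with the largest ratio towards replicate 1 were Mir31, Mir451a, Gm23935, Mir107 and Mir34c. Towards replicate 2 they were Mir293, Mir294, Mir292, Mir205 and Mir200b. Mir31 was 12.4-fold higher (exact interval 10.1 to 15.4) in replicate 1, with 1287 against 99 counts. Mir107, in an intron of Pank1, was 6.31-fold higher (5.69 to 7.01) and Mir34c 5.30-fold higher (3.03 to 9.89) in replicate 1. Gm23935 was 6.70-fold higher (3.73 to 13.1) in replicate 1. Of the runs of 18 nt in its hairpin, 100% recur at another place in the annotated hairpins, and of those in the Mir107 hairpin 18.6%. Reads mapping to several places are left out, so the counts of Gm23935 and Mir107 can be too low. Mir205 was 15.8-fold (7.0 to 44.3) and Mir200b 6.57-fold (4.25 to 10.6) higher in replicate 2; both belong to miRNA families of epithelial cells. In all, 159 of 359 tested genes differed in the per-gene binomial test with Benjamini-Hochberg adjustment, 87 higher in replicate 1 and 72 in replicate 2, and 51 of them by 2-fold or more, 27 and 24 (21 and 36 with library size alone, 30 and 21 with DESeq2 size factors). With library size alone as scaling, which moves each log2 ratio by 0.17, 67 were higher in replicate 1 and 103 in replicate 2; with DESeq2 size factors, 96 and 60. Of the 81 named genes, 11 change sign between these scalings, among them Mir23a, Mir23b, Mir143 and Mir21a, so no direction is given for them. Among genes with 100 or more counts, 33 differed by 2-fold or more.

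**Figure D3:**
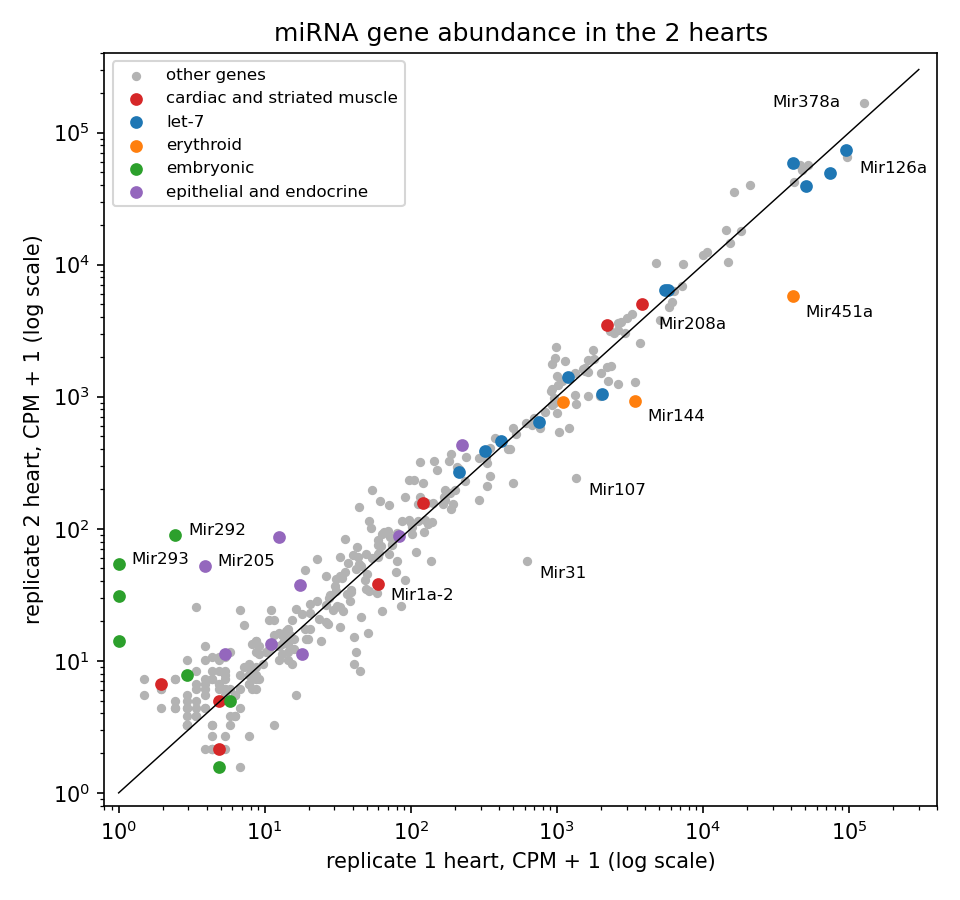
CPM + 1 of each miRNA gene with a mean of 2 CPM or more in the replicate 1 heart (x axis, log scale) and the replicate 2 heart (y axis, log scale), with 5 fixed gene lists in colour and a line of equal values. Mir451a, Mir144, Mir31 and Mir107 lie below the line, and Mir292, Mir293 and Mir205 above it.

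The erythroid genes were higher in replicate 1. Mir451a, which is abundant in red blood cells (chromosome 11, 78073170 to 78073241, plus strand), had 85885 counts in replicate 1 and 10135 in replicate 2, a difference of 8.11-fold (exact interval 7.95 to 8.28). Mir144, which lies beside it (chromosome 11, 78073005 to 78073070), was 4.10-fold higher (3.89 to 4.33) and Mir486, in an intron of Ank1, 1.34-fold higher (1.26 to 1.43). Mir486 shares a run of 22 nt with another hairpin, so its counts do not give the level of the mature miRNA. All 3 erythroid genes differed, also when adjusted over the list alone (3). The list's median log2 ratio of -2.04 stood at the 0.095 percentile of matched lists. Matched lists draw genes independently, while neighbours and family members differed alike here, so this percentile and those of the lists below can overstate how unusual a list is; Mir451a and Mir144 are neighbours, and so are the miR-290 genes. Immune genes went both ways: Mir142 was 2.57-fold higher (2.28 to 2.89) in replicate 1, and Mir150 1.79-fold higher (1.69 to 1.89) in replicate 2. The endothelial genes Mir126a (1.66-fold, 1.65 to 1.67) and Mir221 (2.20-fold, 2.08 to 2.32) were higher in replicate 1, and the median of their list, -0.73, stood inside the central range.

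Genes of the miR-290 cluster, known from embryonic stem cells, were counted almost only in replicate 2. Mir292 (chromosome 7, 3219189 to 3219270, plus strand) had 3 and 157 counts, a ratio of 54.7 (exact interval 18.4 to 268). Mir293 (chromosome 7, 3220343 to 3220422) had 0 and 93 counts and Mir294 0 and 53. Set against a floor of 3 counts in replicate 1, the ratios were 32.4 and 18.5. The exact intervals of the log2 ratio began lower, at 4.69 for Mir293 and 3.86 for Mir294. Of 6 tested embryonic members, 4 were higher in replicate 2 over all genes tested (5 with library size alone) and 4 differed adjusted over the list alone. The list's median log2 ratio was 5.55, at the 100 percentile of matched lists, and 3.00 with the 3 genes at 0 set to the floor. The epithelial and endocrine list had a median log2 ratio of 0.88, at the 99.7 percentile, with 4 of 8 members higher in replicate 2 (4 adjusted over the list alone), among them Mir200c, 1.71-fold higher (1.52 to 1.92).

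The miR-29 list was the only other of the 20 lists outside the central range, with a median log2 ratio of -0.73 at the 1.19 percentile. In simulations without an effect, the list comparison left the central range in 4 of 40, so some lists can lie outside it without cause. Its members went both ways, with Mir29c 1.99-fold higher (1.73 to 2.30) in replicate 1 and the most abundant, Mir29a, 1.16-fold higher (1.12 to 1.19) in replicate 2, so the list's sum was higher in replicate 2. Without genes of several copies, its median of -0.39 stood at the 29.8 percentile. Of the cardiac and striated muscle list, 3 of 7 tested members were higher in replicate 2 (2 with DESeq2 size factors, 4 with library size alone), with Mir208a by 1.18-fold (1.15 to 1.22) and Mir499 by 1.40-fold (1.34 to 1.45), and Mir1a-2 was 1.75-fold higher (1.29 to 2.41) in replicate 1; 4 differed adjusted over the list alone. Of let-7 genes, 5, with Mirlet7i, Mirlet7g and Mirlet7d among them, were higher in replicate 1 and 2 in replicate 2 (7 adjusted over the list alone); with library size alone it was 5 and 7, and with DESeq2 size factors 6 and 1. Of the miR-15 list, 5 were higher in replicate 1, with Mir15b 2.98-fold (2.85 to 3.13), and 1 in replicate 2, Mir195a 2.14-fold (2.03 to 2.26); 7 differed adjusted over the list alone, and it was 6 and 1 with DESeq2 size factors and 4 and 1 with library size alone.

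Neighbouring miRNA genes differed between the hearts more alike than genes drawn at random. Over 64 pairs of neighbours among 264 genes, the mean absolute difference of log2 ratios was 0.58, against 0.98 when ratios were shuffled over genes (one-sided permutation p = 0.00049). Without the erythroid and embryonic lists, left out after seeing the data, it was 0.54 over 61 pairs, against 0.82 (one-sided permutation p = 0.00105). The shuffles were not matched on mean CPM, although the spread of the ratios differed with level. Pairs of 1 cluster can share a gene and are not independent.

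Gene copies and overlapping genes were counted as follows. The 142 Mir genes whose symbols mark several copies held 1.75% ± 0.136 (SD, n = 2) of counts, and the other 1032 Mir genes 98.2% ± 0.133. The share detected was 28.9% and 27.6%. By sequence, the 295 Mir genes that share a run of 18 nt with another hairpin held 49.4% ± 1.69 of counts, with 29.5% detected, and the other 879 held 50.6% ± 1.69, with 27.2% detected. No test was run on these shares. Outside the 64 genes that face a miRNA gene on the other strand, 99.996% of reads lay on the gene's strand in both libraries. Those 64 genes, among them Mir378a, Mir126a, Mir451a, Mir191, Mir30e and Mir486, held 29.0% of sense counts in replicate 1 and 26.6% in replicate 2, and their reads are ambiguous when strand is ignored.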

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

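Among the results above, reads on the strand opposite to the gene enter only the share of reads on the gene's strand. At genes with no annotated miRNA gene on that strand, a scan of 2138 genes found 4 with more than 3 such reads in both libraries. Mir122 had 35 in all, 15 in replicate 1 and 20 in replicate 2, beside 120 and 56 sense counts. Mir130a had 16, as 12 and 4, beside 5732 and 6534 sense counts. Mir203 had 10, with 5 in each library, and Mirlet7b 8, with 4 in each. No explanation was tested for these reads.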

How the results depend on the processing

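Of the main results, 52 values under alternatives kept their direction, their side of the threshold or their size, and 4 moved. Of the 52, 4 are list or neighbour results under another scaling, which cannot move them. Numbers of differing genes were judged by their total. With library size alone that total counts as kept, though its balance turned to 67 higher in replicate 1 and 103 in replicate 2. The top 10 genes held 68.6% of counts without regard to strand, where genes facing another miRNA gene lose their reads, and 24.1% of all reads, a change that follows from the larger denominator. The biological coefficient of variation was 10.8% from the median DESeq2 gene-wise dispersion, and the cause was not tested. With 100 or more counts required, 33 genes differed 2-fold or more in place of 51, as fewer genes were tested. The top 10 share was 66.1% to 67.2% and the number of detected genes 355 to 374 with either library left out. Of the 159 differing genes, 147 were shared with DESeq2 size factors, 141 with library size alone and 139 with counts without regard to strand. Pearson's r stayed between 0.951 and 0.980, including the 2 alternatives chosen after seeing the data, without the erythroid list and without genes that share a run of 18 nt. The neighbour result kept a permutation p of 0.00105 or less in the 5 settings that could move it, one of them chosen after seeing the data. Of single lists and genes, 242 values were the same, 40 of them list medians under another scaling, whose percentiles cannot change, and 17 counts of detected members moved, in the skeletal muscle, erythroid, embryonic and testis lists. Without regard to strand 1 erythroid gene was detected, so that list could not be assessed; 4 lists lay outside the central range as before, with the immune list in its place, and the miR-29 list came inside it with single-copy genes, which leaves 3 lists outside in place of 4. Depth limits lists near the floor of 1.45 to 1.70 CPM, such as testis and skeletal muscle. No paired analysis was possible because there is 1 group.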

Other observations

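Of the tests in this part, those of the leukocyte genes, of the miR-290 cluster, of runs of 22 nt, of runs of 18 nt in let-7 or without the Sfmbt2 cluster, and of gene families were chosen after the result was seen; those of GC content and, for the erythroid and muscle genes and all list members, of runs of 18 nt were written before. Shared runs were sought among annotated hairpins only, and copies elsewhere in the genome were not searched. Runs of 22 nt were taken up once abundant genes such as Mirlet7i were seen to share 18 nt. The bounds that would speak against the family and the miR-302 explanation, and the way the tests of shared runs are judged together, were changed after the results were seen. The genes named here that the rule did not select were chosen after their values were seen.

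The miR-34 family, whose members share a seed sequence, had 3 members, at separate loci, that were higher in replicate 1. Mir34a on chromosome 4 was 2.38-fold higher (exact interval 2.27 to 2.5), Mir34c on chromosome 9 5.30-fold (3.03 to 9.89) and Mir449a on chromosome 13 3.65-fold (2.37 to 5.81). Mir34b went the other way with 1 and 8 counts, too few for the per-gene test, and Mir449b and Mir449c had 0 counts in both libraries. Neighbouring genes on 1 strand did not always keep 1 ratio. Mir143 exceeded its neighbour Mir145a by 37.2 times (35.7 to 38.8) in replicate 1 and 22.7 times (21.9 to 23.5) in replicate 2. Mir451a exceeded Mir144 by 12.2 times (11.9 to 12.5) and 6.15 times (5.83 to 6.48). Mir23b, which lies on another chromosome than Mir23a, exceeded it by 1.10 times in both hearts.

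The erythroid genes differed 6.80-fold in sum (6.68 to 6.92) between the hearts. The trend on hairpin GC content over the 264 genes with a mean of 10 CPM or more left Mir451a at a log2 ratio of -3.07, from -3.02 before. That is -5.94 robust SD and argues against hairpin GC content as the whole cause. The trend held 2.66% of the variance, and the GC content of the reads themselves was not tested. Of Mir451a and Mir144, 0 share a run of 18 nt with another hairpin, which argues against reads shared with another hairpin for these 2, while Mir486 does share such a run. If whole blood left in the tissue were the source, leukocyte genes would move with Mir451a; 1 of 3 did (Mir142), while Mir150 and Mir223 (2.12-fold, 1.59 to 2.85) were higher in replicate 2. Blood rich in red cells may still differ between the hearts and cannot be told apart from other sources by these genes, since resident cells may also carry them; no biological explanation was tested.

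The miR-1 and miR-133 genes had few counts. Reads mapping to several places are in no gene's count. Of the 6 genes, 5 share a run of 22 nt with another hairpin, so reads within such a run can be left out. How many of the reads left out came from these genes cannot be read from the counts, so this candidate explanation of the low counts stays open. All 6 of these genes share a run of 18 nt with another hairpin and 0 of Mir208a, Mir208b and Mir499 do (Fisher's exact test, two-sided, p = 0.0119), but all 6 share it with another of the 6, so their grouping by family fixed that outcome and the test decides nothing. Over all list members, sharing genes had lower medians with runs of 18 nt and of 22 nt (permutation p = 1e-05 for both, the smallest the shuffles can give), and without the Sfmbt2 cluster the medians were 27.7 against 27.2 CPM at 18 nt (permutation p = 1) and 18.6 against 34.7 CPM at 22 nt (permutation p = 0.507). Within the let-7 list, the 6 genes that share a run of 22 nt had a lower mean, 1516 CPM, than the 6 others, 41405 CPM (exact permutation p = 0.00649), with ranges that overlap (240 to 6071 and 1537 to 84244 CPM), while at 18 nt the 9 sharing genes had a mean of 22751 CPM and the 3 others 17588 CPM (exact permutation p = 0.805). No biological explanation was tested.

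The miR-290 cluster had 3 counts over 6 genes in replicate 1 and 335 in replicate 2. The lower bound of its log2 ratio, 5.31, argues against counting error, and 1 of the 6 genes, Mir291a, shares a run of 18 nt with another hairpin, which argues against reads shared with another hairpin for the other 5; that gene held 6.87% of the counts in replicate 2, which decides nothing because reads mapping to several places are left out. Material that also carries the miR-302 cluster cannot be told apart: Mir302a, Mir302b, Mir302d and Mir367 had 22 and 20 counts, with an upper bound of 0.87 on the log2 ratio, but none had a mean over 4.39 CPM, and the ratio of the 2 clusters in such material was not measured. Reads from another tissue's library cannot be told apart here, since of the liver, neuronal, testis and skeletal muscle lists 2 were higher in replicate 2 (neuronal 2.26-fold, 1.87 to 2.76; skeletal muscle 3.13-fold, 1.43 to 7.57) and the others had intervals that hold no difference. Stem-cell material with the miR-290 cluster alone was not tested, and no biological explanation was tested.

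A hypothesis is that sequence shared within a family, or reads exchanged between its members, may make distant relatives differ alike. Over 105 pairs of 1 family number, over 50 kb apart or on different chromosomes, the mean absolute difference of log2 ratios was 0.48, against 0.97 for shuffled ratios (one-sided permutation p = 0.00062). These shuffles were not matched on mean CPM. For the 104 pairs on different chromosomes the permutation p was 0.00054, and without let-7, over 54 pairs, 0.00607. For the 9 pairs of genes that share no run of 18 nt, the difference was 1.03 against 0.97 (one-sided permutation p = 0.646). Whether 9 pairs could show such an effect was not simulated, so shared sequence and exchanged reads cannot be told apart.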
